A study of Homo sapiens with 6 samples.

How the data were processed

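Total RNA of a human kidney cell line was measured on 6 one-colour Affymetrix arrays, with 2 each for the empty vector (mock), hIMP1 wt and hIMP1 Dmut. Groups were taken from the labels' sample descriptions and replicate numbers from the sample titles. The platform is known from the header of the annotation table. The deposited values are intensities on a linear scale, 1 per probe set. The authors' software and scaling are not given in the sources used here. In the deposited intensities the trimmed mean, with 2% taken off each end, was 150.02 on every array while the medians differed, so each array appears to have been scaled by a single factor. All values were above 0, and no detection calls were used here. The ratio of 3' to 5' control probe sets lay between 1.03 and 1.17 for GAPDH and between 1.44 and 1.67 for ACTB. No duplicate array was found: the highest correlation between arrays was 0.980, between arrays of different groups.

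The 62 control probe sets were left out. Values were used as deposited, without further scaling, as log2 of the intensity plus an offset of 9.04, the pooled lower quartile of all values. The offset makes fold changes of dim probe sets smaller. Probe sets were kept when their mean log2 value over the 6 arrays was at or above the median of those means (5.18), which left 27307 of 54675. Gene symbols came from the annotation table, in which 41091 probe sets had 1 symbol, 1801 several and 11721 none. Of those with 1 symbol, 41037 had a gene identifier in the RefSeq gene table of assembly GRCh38.p14, and 0 symbols changed. No gene was named from a probe set with several symbols, which leaves out HSPA1A and HSPA1B. No coordinates are given, since the files name no genome build.

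Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend. All 6 arrays entered a single fit with a coefficient per group, which leaves 3 residual degrees of freedom, to which the prior added 7.03. Tests were two-sided, with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. Errors given with log2 changes are standard errors, and intervals are at 95%. With the median standard error, an unadjusted p of 0.05 needs a log2 change of 0.62. Simulated data of hIMP1 wt minus mock over 27307 probe sets, with 200 changed each time and arrays drawn independently, tested the fit. It called 5.67% of changes of 1 on the log2 scale, 48.6% of changes of 2 and 88.9% of changes of 4, with 1.8 false calls a simulation. These shares hold for 200 changed probe sets, and a change on its own would be called less often after adjustment.

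Before the data were examined, 27 gene lists were written from general knowledge. Each gene was represented by its brightest kept probe set with 1 symbol (12269 genes). The 25 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The second form also uses only the 3 residual degrees of freedom, so it can lose a call whatever the correlation. For the Golgi list with hIMP1 Dmut the estimate, -0.0167, lay below the preset, yet the adjusted p went from 0.0176 to 0.882. The lists were also tested with fry, without adjustment. Each median was also set against 10000 random lists matched for expression and drawn gene by gene. The IMP family had too few genes and is given gene by gene, and the mitochondrially encoded transcripts had too few measured genes to be tested. In simulated data a shift of 0.2 in the unfolded protein response list was called in 9 of 10 simulations. There were 0 calls among 230 tests of other lists, with the secretory list left out. Genes and arrays were drawn independently there, while the estimated correlation within measured lists reached 0.81. The simulations therefore do not give the rate of false list calls in these data. Per comparison and direction, the rule for named genes took up to 12 called genes whose groups of arrays did not overlap, largest change first, or, where fewer were called, these and the genes of smallest p up to 8. It also took the IMP family, all measured IMP1 targets, and the 4 members of each described list with the largest moderated statistic. Where another kept probe set of a named gene had the opposite sign in the comparison described, the text says so.

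The alternatives were quantile and median scaling, offsets at the 10th percentile and the median, no filter, only probe sets above the 75th percentile, the replicate number as a block, only the 4 arrays compared, a prior without trend or with a robust fit, each array left out in turn, an estimated correlation, the mean of all probe sets of a gene, and other rules for a call. Cyclic loess scaling, the heat shock list without HSPA6, the unfolded protein response list without its secretory members, and the block together with an estimated correlation were added after seeing the data. Groups of 2 arrays are too small for a count of other splits of the samples. The tests of technical explanations were all chosen after the results were seen, and some of them replaced an earlier form after its outcome was known.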

Results

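Gene expression was measured in a human kidney cell line after transfection with an empty vector (mock), with a construct labelled hIMP1 wt, or with a construct labelled hIMP1 Dmut. IMP1, the product of IGF2BP1, is an RNA-binding protein that associates with selected mRNAs in cytoplasmic granules. The labels do not say what Dmut stands for, and they do not name the cell line. Total RNA from each of 6 samples was hybridised to its own 1-colour oligonucleotide array, with 2 arrays for each of the 3 groups. Each array gave 54675 intensities on a linear scale. The median intensity lay between 26.7 on hIMP1 wt replicate 2 and 33.7 on hIMP1 Dmut replicate 2, and the lower quartile between 7.4 and 9.94. The number of arrays limits the precision of every value. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The arrays carry a replicate number, 1 or 2, and arrays of the same number were more alike (r across 27307 probe sets between 0.970 and 0.980) than arrays of the same group (r between 0.963 and 0.964). Changes within the arrays numbered 1 and within those numbered 2 are therefore given for IGF2BP1, for HSPA6, for the lists called, and for the genes of smallest p whose changes within the 2 numbers differed by over 3 times. Probe sets are not independent replicates.

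The transfected gene itself was read by 2 probe sets. IGF2BP1 had an intensity of 269 with the empty vector, 276 with hIMP1 wt and 277 with hIMP1 Dmut at its brighter probe set, and the log2 change was 0.03 ± 0.25 (SE) for hIMP1 wt and 0.05 ± 0.25 for hIMP1 Dmut. Within the arrays numbered 1 and 2 those changes were -0.03 and 0.09 for hIMP1 wt and 0.20 and -0.09 for hIMP1 Dmut. At the dimmer probe set of IGF2BP1 the mean intensity was 141 ± 67.1 (SD, n = 2) with the empty vector, 195 ± 82.1 with hIMP1 wt and 199 ± 68.7 with hIMP1 Dmut. The log2 changes there were 0.46 ± 0.39 and 0.51 ± 0.39, and they were positive within both numbers, at 0.41 and 0.51 for hIMP1 wt and 0.38 and 0.64 for hIMP1 Dmut. None of the 4 changes passed in the limma fit (adjusted p = 1), whose residual spread includes the difference between the replicate numbers. The files do not say which part of the transcript these probe sets read, and a construct that lacks that part would not be seen, so they do not check the transfection. The other members of the family did not pass the test either. The brightest probe set of IGF2BP2 differed from the empty vector by 0.03 ± 0.24 with hIMP1 wt and by -0.13 ± 0.24 with hIMP1 Dmut, with a change of the opposite sign (0.06) at another probe set for hIMP1 Dmut. The brightest probe set of IGF2BP3 differed by -0.004 ± 0.16 and 0.08 ± 0.16, and its other probe sets gave 0.10 and 0.17 with hIMP1 wt and, at 1 of them, -0.20 with hIMP1 Dmut.

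The comparison of hIMP1 wt with the empty vector asks which transcripts differ when cells receive the construct labelled as wild type. HSPA6, the strictly inducible member of the HSP70 chaperone family, rose in this comparison. Its brighter probe set had a mean intensity of 15.8 ± 18.1 (SD, n = 2) with the empty vector and 550 ± 136 with hIMP1 wt. On the log2 scale with an offset the change was 4.69 ± 0.44 (SE), or 25.8-fold (limma, adjusted p = 0.0119). A dimmer probe set of HSPA6 went from 8.07 ± 7.78 to 292 ± 89.4, a log2 change of 4.18 ± 0.35 (adjusted p = 0.0071). The brighter probe set of HSPA6 was higher within the arrays numbered 1 (4.12) and within those numbered 2 (5.26). These 2 probe sets were the only ones of 27307 past the threshold, and none was past it downwards. Mock intensities of HSPA6 lay near the bottom of the scale, so its fold depends on the offset, and the near-identical pseudogene HSPA7 could add to its signal. The call of the brighter probe set was lost with an offset at the 10th percentile (adjusted p = 0.0829), with only the 4 arrays compared (0.234), without an intensity trend in the variance prior (0.419), and without hIMP1 Dmut replicate 1 (0.209) or replicate 2 (0.213). Its log2 change was 5.37 with that offset, 4.69 in the other 4 of these fits, and 3.68 with an offset at the median (adjusted p = 0.00274), so the fold holds only for the offset used.

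**Figure D1:**
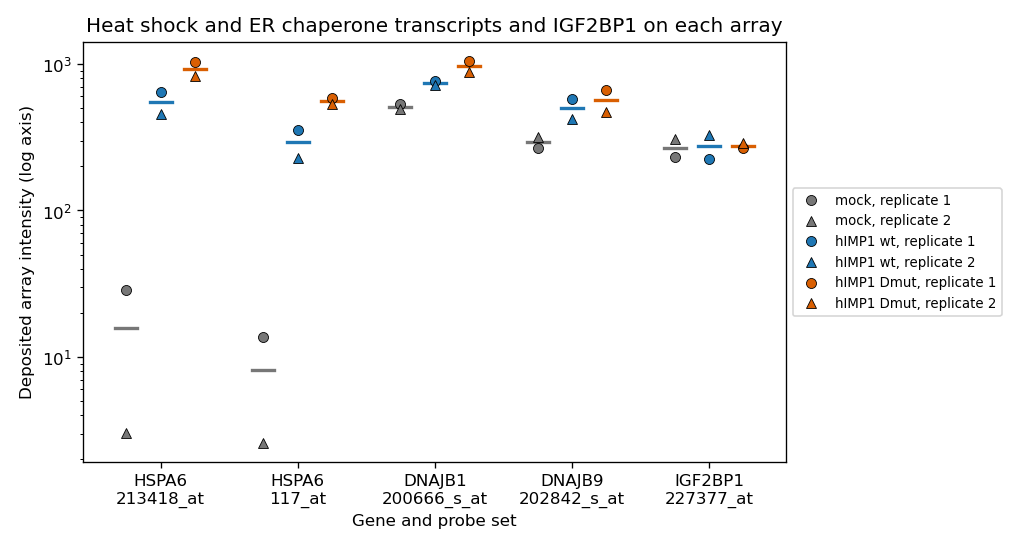
Deposited intensity (log axis) on each of the 6 arrays for 2 probe sets of HSPA6 and 1 each of DNAJB1, DNAJB9 and IGF2BP1; circles are arrays numbered 1, triangles arrays numbered 2, and each bar is the mean of the 2 arrays of a group. At the brighter probe set of HSPA6, the mock arrays sit at 28.6 and 3.02, the hIMP1 wt arrays at 646 and 454, and the hIMP1 Dmut arrays at 1030 and 824, while the IGF2BP1 group means lie between 269 and 277.

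The unfolded protein response list, which holds chaperones, sensors and degradation factors of the endoplasmic reticulum (ER), was higher with hIMP1 wt. Of its 31 measured genes 27 were higher and 4 lower, and the median log2 change was 0.20 (camera, adjusted p = 6.29e-09 with a preset correlation between genes; adjusted p = 0.545 with an estimated correlation). The median was 0.34 within the arrays numbered 1 and 0.08 within those numbered 2. None of the 31 genes passed the threshold alone, over all genes or adjusted over the list alone. The members with the largest statistics were DNAJB9, an ER co-chaperone (0.75 ± 0.24), HYOU1, an ER chaperone (0.46 ± 0.21), EIF2AK3, the ER stress kinase PERK (0.55 ± 0.25), and EDEM1, which takes misfolded glycoproteins to degradation (0.41 ± 0.20). The heat shock list was also higher: 15 of 20 genes were higher, with a median of 0.15 (adjusted p = 5.17e-05; 0.0115 without HSPA6; adjusted p = 0.905 with an estimated correlation), and 0.07 and 0.18 within the arrays numbered 1 and 2. The call was kept with each array left out, but the median was 0.07 without hIMP1 wt replicate 1 and 0.08 without mock replicate 2. In that list 1 gene, HSPA6, passed over all genes and 1 adjusted over the list alone. DNAJB1, the HSP40 partner of HSP70, had a log2 change of 0.54 ± 0.18, BAG3 of 0.31 ± 0.25 and HSPH1 of 0.25 ± 0.20, none of them past the threshold. In the list of the secretory pathway and ER translocation, 44 of 60 genes were higher, with a median of 0.07 (adjusted p = 4.97e-04; adjusted p = 0.981 with an estimated correlation) and 0.07 and 0.08 within the arrays numbered 1 and 2. None of the 60 passed alone, over all genes or adjusted over the list alone. KDELR3, an ER retrieval receptor, had a log2 change of 0.49 ± 0.21, the translocon-associated SSR3 of 0.28 ± 0.17 and SSR1 of 0.32 ± 0.19, and the coat protein gene COPB2 of 0.24 ± 0.17, with the opposite sign at another probe set of SSR1 (-0.09). These 3 of 25 lists were called, all upwards. By fry, the unadjusted p was 0.0805 for the unfolded protein response, 0.222 for heat shock and 0.322 for the secretory list. Only the Golgi list, not called by camera, had a fry p under 0.05 in this comparison (0.0375). The secretory call was lost without mock replicate 1 (median 0.02, adjusted p = 0.0794) or without hIMP1 wt replicate 2 (0.03, adjusted p = 0.163). Cyclic loess scaling called 4 lists, 3 upwards and 1 downwards.

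Outside these lists, the genes with the smallest p were all at an adjusted p of 1. On the higher side with hIMP1 wt they were ANHX (1.70 ± 0.45), ARHGDIB (1.45 ± 0.45), BCL6B (1.43 ± 0.46), C11orf96 (1.22 ± 0.38) and INHBB, a subunit of activin and inhibin (1.22 ± 0.41). On the lower side they were BICDL1 (-1.66 ± 0.38), PRR35 (-1.62 ± 0.50), POU5F1B (-1.38 ± 0.38), CATSPER3 (-1.30 ± 0.40), ST6GALNAC6 (-1.27 ± 0.38), LOC100505711 (-1.11 ± 0.34), TAF15, an RNA-binding protein (-0.89 ± 0.22), and the potassium-chloride cotransporter gene SLC12A7 (-0.76 ± 0.20). Another probe set of TAF15 went the other way (0.21). Many of these signals were low against array medians of 26.7 to 33.7, so such changes depend on the offset. BICDL1, POU5F1B, CATSPER3 and ST6GALNAC6 had mean intensities of 13.3, 11.8, 14.5 and 11 with hIMP1 wt. ANHX, BCL6B and INHBB had 16.5, 18.8 and 13.2 with the empty vector. TAF15 and SLC12A7 were brighter, at 256 and 253 with hIMP1 wt, as was C11orf96, at 182 with the empty vector. The change of ARHGDIB was 2.24 within the arrays numbered 1 and 0.66 within those numbered 2. Over all probe sets, 281 had an unadjusted p under 0.05, 114 of them higher and 167 lower, where 1365 would be expected by chance. This count depends on the model, which leaves differences between the replicate numbers in its residual spread.

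The comparison of hIMP1 Dmut with the empty vector asks the same of the second construct. HSPA6 rose here as well, to a mean intensity of 929 ± 148 (SD, n = 2) at its brighter probe set, a log2 change of 5.45 ± 0.44 (SE), or 43.7-fold at the offset used (limma, adjusted p = 0.00292). That change was 6.14 with an offset at the 10th percentile and 4.41 with an offset at the median. At the dimmer probe set the intensity was 558 ± 33.3 and the log2 change 5.13 ± 0.35 (adjusted p = 0.00102). The changes at the brighter probe set were 4.79 within the arrays numbered 1 and 6.11 within those numbered 2. Again these were the 2 probe sets past the threshold, none of them lower. The call of HSPA6 at that probe set was lost without an intensity trend (adjusted p = 0.153) and without hIMP1 Dmut replicate 1 (0.377) or replicate 2 (0.251), while its log2 change was 5.45, 5.29 and 5.61 in these fits. In the heat shock list 12 of 20 genes were higher and 8 lower, with a median of 0.05 (camera, adjusted p = 0.00998; 0.246 without HSPA6; adjusted p = 0.882 with an estimated correlation), and the median was 0.25 within the arrays numbered 1 and -0.15 within those numbered 2. It was -0.115 without hIMP1 Dmut replicate 1 (adjusted p = 0.8) and 0.28 without hIMP1 Dmut replicate 2. DNAJB1 had a log2 change of 0.90 ± 0.18 and passed with HSPA6 when adjusted over the list alone, 2 genes against 1 over all genes. BAG3, a co-chaperone of HSP70, had a log2 change of 0.67 ± 0.25, and STIP1, which links HSP70 to HSP90, of -0.33 ± 0.17.

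Other lists moved upwards with hIMP1 Dmut. In the unfolded protein response list 22 of 31 genes were higher, with a median of 0.10 (adjusted p = 0.00153; adjusted p = 0.882 with an estimated correlation), which was 0.23 within the arrays numbered 1 and -0.04 within those numbered 2. That call was lost without mock replicate 1 (median 0.09, adjusted p = 0.331) or hIMP1 Dmut replicate 1 (median 0.07, adjusted p = 0.389), and the median was 0.19 without hIMP1 Dmut replicate 2. DNAJB9 (0.92 ± 0.24), XBP1, a transcription factor of the response (0.57 ± 0.20), EIF2AK3 (0.63 ± 0.25) and HERPUD1 (0.33 ± 0.21) had its largest statistics. In the Golgi list 32 of 47 genes were higher, with a median of 0.08 (adjusted p = 0.0176; adjusted p = 0.882 with an estimated correlation) and 0.10 and 0.08 within the arrays numbered 1 and 2. Its leading members were FURIN, a proprotein convertase (0.73 ± 0.33), COG2 (0.34 ± 0.18), COG8 (0.42 ± 0.27, but -0.23 at another probe set) and GOLGA5 (0.29 ± 0.19), and the call was lost without mock replicate 1, mock replicate 2 or hIMP1 Dmut replicate 1, where the adjusted p reached 0.213 while the median stayed between 0.09 and 0.11. Of 31 immediate early genes, which respond first to stimulation, 26 were higher, with a median of 0.20 (adjusted p = 5.79e-04; adjusted p = 0.882 with an estimated correlation) and 0.10 and 0.38 within the arrays numbered 1 and 2. EGR1 had a log2 change of 1.08 ± 0.38, FOSL1 of 0.89 ± 0.40 and FOSL2 of 0.87 ± 0.41, but NR4A1 of -0.91 ± 0.36. The immediate early call was lost without mock replicate 2 (median 0.08, adjusted p = 0.4) or hIMP1 Dmut replicate 1 (median 0.24, adjusted p = 0.137), and the median was 0.37 without mock replicate 1.

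The lists called downwards with hIMP1 Dmut had larger median changes within the arrays numbered 2 than within those numbered 1. Of 68 nuclear genes of oxidative phosphorylation 59 were lower, with a median of -0.15 (adjusted p = 1.1e-05; adjusted p = 0.882 with an estimated correlation), which was -0.05 within the arrays numbered 1 and -0.26 within those numbered 2. UQCRC1 (-0.45 ± 0.23), COX4I1 (-0.26 ± 0.19), NDUFS3 (-0.23 ± 0.16) and SDHA (-0.27 ± 0.20) led it, and the call was lost without mock replicate 2 (adjusted p = 0.805). Of 27 proteasome genes 22 were lower, with a median of -0.12 (adjusted p = 0.0041; adjusted p = 0.882 with an estimated correlation), 0.01 within the arrays numbered 1 and -0.26 within those numbered 2. PSMA7 (-0.33 ± 0.19), PSMD8 (-0.25 ± 0.19), PSMD4 (-0.23 ± 0.17) and PSMD1 (-0.24 ± 0.20) led that list. Its call was lost without mock replicate 2 or hIMP1 Dmut replicate 2 (adjusted p up to 0.751) and under quantile or cyclic loess scaling (adjusted p = 0.18 and 0.101, with a median of -0.08 in both). Of 68 cell cycle genes 54 were lower, with a median of -0.10 (adjusted p = 0.00153; adjusted p = 0.882 with an estimated correlation), -0.07 within the arrays numbered 1 and -0.14 within those numbered 2. The mitotic kinase genes PLK1 (-0.75 ± 0.26) and AURKB (-0.66 ± 0.32), with CENPA (-0.49 ± 0.29) and CDCA8 (-0.30 ± 0.18), led it, and the call was lost without mock replicate 2 or hIMP1 Dmut replicate 1 (adjusted p up to 0.502). Of 53 cytosolic ribosomal protein genes 50 were lower, with a median of -0.09 (adjusted p = 0.00489; adjusted p = 0.894 with an estimated correlation), but the median was 0.16 within the arrays numbered 1 and -0.30 within those numbered 2, and its sign turned under cyclic loess scaling (0.02) and without mock replicate 2 (0.10), and its call was lost under quantile scaling (adjusted p = 0.942) and without hIMP1 Dmut replicate 2 (median -0.05, adjusted p = 0.663). RPL8 (-0.32 ± 0.21), FAU (-0.21 ± 0.20) and RPS19 (-0.19 ± 0.20) were lower and RPL36A higher (0.54 ± 0.37). Of the random lists matched for expression, 15.63% had a lower median than the ribosomal list. That share was 0% for oxidative phosphorylation, 1.51% for the proteasome and 0.06% for the cell cycle. Random lists were drawn gene by gene, while the estimated correlation within these lists was 0.81, 0.51, 0.41 and 0.20, in the same order. The shares therefore do not say how often a list of correlated genes would reach such a median. Without mock replicate 1 the medians of these 4 lists, in the same order, were -0.27, -0.21, -0.24 and -0.25. Without mock replicate 2 those of the first 3 were -0.01, -0.03 and -0.0086. The cell cycle median was -0.05 without hIMP1 Dmut replicate 1 and -0.16 without hIMP1 Dmut replicate 2, and the proteasome median -0.06 without the latter. On hIMP1 Dmut replicate 2 the median of 5 blood cell markers, relative to each gene's mean over the arrays, was 0.54, against -0.44 to 0.23 on the other 5 arrays. None of the genes of these 4 lists or of the unfolded protein response, Golgi and immediate early lists passed alone, over all genes or adjusted over the list alone. With 8 lists called, 4 went up and 4 down. Quantile and cyclic loess scaling each called 6, with 4 up and 2 down. By fry, the unadjusted p was 0.0229 for the Golgi list and at least 0.157 for the other called lists. It was also under 0.05 for ubiquitin conjugation (0.0314), which camera did not call.

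**Figure D2:**
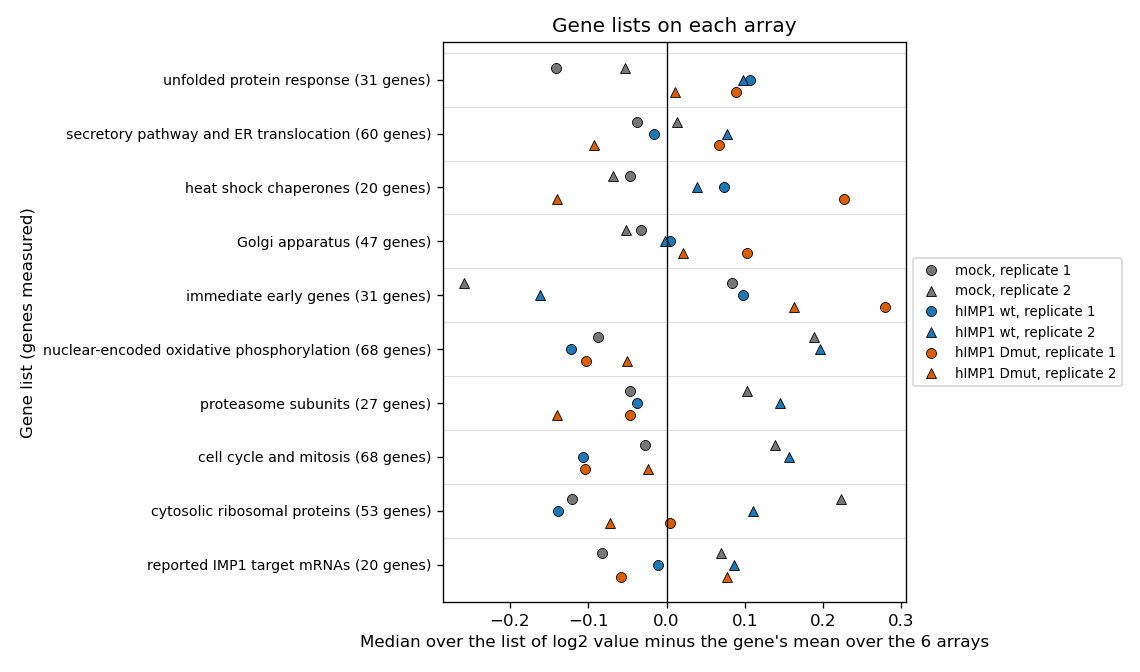
Median over each gene list of the log2 value minus the gene's mean over the 6 arrays, for 10 lists; circles are arrays numbered 1, triangles arrays numbered 2, grey is mock, blue hIMP1 wt and orange hIMP1 Dmut, without error bars. The unfolded protein response list sits at -0.14 and -0.05 on the mock arrays and between 0.01 and 0.11 on the other 4, whereas oxidative phosphorylation sits at 0.19 and 0.20 on the mock and hIMP1 wt arrays numbered 2 and between -0.12 and -0.05 on the other 4.

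Genes with the smallest p in this comparison other than the chaperones were again all at an adjusted p of 1. With hIMP1 Dmut, INHBB (1.71 ± 0.41), ANHX (1.68 ± 0.45), NKX6-3 (1.48 ± 0.38), PARD6G-AS1 (1.45 ± 0.38) and KLHL25 (1.22 ± 0.34) were on the higher side. PLEKHO2 (-1.64 ± 0.55), NBL1 (-1.54 ± 0.49), HM13 (-1.36 ± 0.45), ZNF579 (-1.25 ± 0.37), the syntaxin gene STX4 (-0.81 ± 0.23), the RNA helicase gene DDX39A (-0.76 ± 0.19), the centromere protein gene CENPM (-0.75 ± 0.22) and RILPL1 (-0.73 ± 0.24) were on the lower side. Another probe set of HM13 went the other way (0.67). INHBB, ANHX, NKX6-3, PARD6G-AS1 and KLHL25 had mean intensities between 13.2 and 24.6 with the empty vector, and NBL1 19.1 with hIMP1 Dmut, so these changes rest on low signals. Within the arrays numbered 1 and 2 the changes of HM13 were -2.50 and -0.22, and those of NBL1 -0.61 and -2.48. Over all probe sets, 387 had an unadjusted p under 0.05, 231 of them higher and 156 lower, against 1365 expected by chance, in the same model without the replicate number.

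The direct comparison of the constructs asks what distinguishes hIMP1 wt from hIMP1 Dmut. No probe set passed the threshold (limma, 0 of 27307), and 337 had an unadjusted p under 0.05, against 1365 expected by chance, in the model without the replicate number. HSPA6 was lower with hIMP1 wt by a difference of -0.76 ± 0.44 (SE) at the brighter probe set (95% interval -1.74 to 0.22) and -0.94 ± 0.35 at the dimmer (95% interval -1.71 to -0.18), both at an adjusted p of 1. DNAJB1 differed by -0.37 ± 0.18 (adjusted p = 1). The unfolded protein response and heat shock lists, called against the empty vector, were not called between the constructs (medians 0.07 and 0.01, camera, adjusted p = 0.106 and 0.728). Without hIMP1 Dmut replicate 1 both were called upwards (medians 0.09 and 0.14, adjusted p = 0.023 and 0.0181), and without hIMP1 Dmut replicate 2 the heat shock list was called downwards (median -0.22, adjusted p = 0.017). TAF15 had the smallest p (-1.11 ± 0.22), with an intensity of 256 with hIMP1 wt, 555 with hIMP1 Dmut and 477 with the empty vector, and its other 2 probe sets had the same sign. Also lower with hIMP1 wt, none past the threshold, were ST6GALNAC6 (-1.40 ± 0.38), the cardiac actin gene ACTC1 (-1.37 ± 0.33), BICDL1 (-1.31 ± 0.38), CTNNBIP1, an inhibitor of beta-catenin (-1.29 ± 0.35), CATSPER3 (-1.29 ± 0.40), PGF, placental growth factor (-0.77 ± 0.23), and SLC12A7 (-0.66 ± 0.20). On the higher side, likewise at an adjusted p of 1, were the histone methyltransferase gene SETD1A (1.41 ± 0.45), ALOX12-AS1 (1.35 ± 0.37), DAGLA (1.12 ± 0.38), STPG3 (0.99 ± 0.33), FBXO6 (0.74 ± 0.26), RNF167 (0.66 ± 0.23), STIP1 (0.53 ± 0.17) and TOR1A (0.48 ± 0.17). Within the arrays numbered 1 and 2 the differences were 0.20 and 1.13 for RNF167 and -0.35 and -1.18 for PGF. Some of these differences rest on low signals. ST6GALNAC6, BICDL1 and CATSPER3 had mean intensities of 11, 13.3 and 14.5 with hIMP1 wt, and SETD1A, ALOX12-AS1 and DAGLA 17.3, 18.5 and 21.3 with hIMP1 Dmut.

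Between the constructs 7 lists were called, 4 higher and 3 lower with hIMP1 wt, and none of their genes passed alone, over all genes or adjusted over the list alone. Every one of these calls was lost with an estimated correlation (adjusted p = 0.697 for each). By fry, the unadjusted p of these 7 lists was at least 0.295. Only the Golgi list, not called by camera, had a fry p under 0.05 between the constructs (0.0452). All 27 proteasome genes were higher with hIMP1 wt (median 0.14, adjusted p = 2.21e-05), led by PSMD6 (0.28 ± 0.18), PSMD1 (0.27 ± 0.20), PSMD3 (0.25 ± 0.20) and PSMA5 (0.23 ± 0.21). So were 60 of 68 genes of oxidative phosphorylation (median 0.10, adjusted p = 1.55e-05), with NDUFA1 (0.40 ± 0.25), ATP5F1D (0.38 ± 0.23), UQCRC1 (0.35 ± 0.23) and UQCR10 (0.28 ± 0.18), and 50 of 68 cell cycle genes (median 0.10, adjusted p = 6.27e-04), with PLK1 (0.48 ± 0.26), KIF20A (0.44 ± 0.30), CDC25C (0.31 ± 0.22) and CDC25B (0.29 ± 0.22). In the secretory list 43 of 60 were higher (median 0.07, adjusted p = 0.0274), among them OST4 (0.33 ± 0.18), DAD1 (0.33 ± 0.20) and SRPRA (0.25 ± 0.20) but not SEC23A (-0.34 ± 0.22, with 0.12 at another probe set). Within the arrays numbered 1 these 4 medians, in the same order, were -0.0018, -0.02, 0 and -0.04, and within those numbered 2 they were 0.29, 0.24, 0.19 and 0.17. Without hIMP1 wt replicate 1 the first 3 were 0.24, 0.28 and 0.24, and without hIMP1 wt replicate 2 all 4 were 0.05, -0.06, -0.01 and 0.0069. Without hIMP1 Dmut replicate 1 the cell cycle median was 0.04 and the secretory one 0.12, and without hIMP1 Dmut replicate 2 the proteasome, cell cycle and secretory medians were 0.09, 0.16 and 0.0099. Under the 3 other scalings the medians ranged from 0.0704 to 0.1823 for the proteasome and from 0.0311 to 0.1428 for oxidative phosphorylation. They ranged from 0.0524 to 0.1409 for the cell cycle and from 0.0265 to 0.1138 for the secretory list. Of the random lists matched for expression, 92.74% had a lower median than the secretory list, and at least 99.88% for the other 3. As these were drawn gene by gene, the shares do not say how often a list of correlated genes would reach such a median.

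Lower with hIMP1 wt than with hIMP1 Dmut were 26 of 31 immediate early genes (median -0.14, adjusted p = 0.00689), with EGR4 (-1.31 ± 0.48), EGR1 (-0.69 ± 0.38), EGR3 (-0.69 ± 0.48) and NR4A3 (-0.57 ± 0.40). With an estimated correlation the adjusted p was 0.697 for this list, as for the histone and KRAB zinc finger lists. The same direction was found for 13 of 14 histone genes that are expressed with DNA replication (median -0.23, adjusted p = 0.0491), with H2AC14 (-0.80 ± 0.47), H4C8 (-0.65 ± 0.74), H2BC5 (-0.44 ± 0.39) and H4C4 (-0.44 ± 0.38), and for 46 of 76 KRAB zinc finger genes (median -0.08, adjusted p = 0.0498), with ZNF214 (-0.86 ± 0.48), ZNF136 (-0.52 ± 0.28) and ZNF85 (-0.32 ± 0.18) but not ZNF33B (0.45 ± 0.24). Other probe sets of H2BC5 (0.08), ZNF85 (0.19) and ZNF33B (-0.10) had the opposite sign. The medians of these 3 lists were -0.13, -0.19 and -0.06 within the arrays numbered 1 and -0.29, -0.40 and -0.15 within those numbered 2. They were -0.29, -0.65 and -0.15 without hIMP1 wt replicate 1, -0.06, 0.18 and -0.0071 without hIMP1 wt replicate 2, and -0.22, -0.39 and -0.14 without hIMP1 Dmut replicate 2. Without hIMP1 Dmut replicate 1 the first 2 were -0.23 and -0.0087. Every one of the 7 calls was lost without hIMP1 wt replicate 2, and quantile scaling called 2 lists, 1 in each direction, where cyclic loess called 3, with 1 higher and 2 lower, and median centring 6, with 4 higher and 2 lower.

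The list of mRNAs reported as IMP1 targets did not stand apart in any comparison. Of its 30 members 20 were measured, and camera gave a median of -0.01 with hIMP1 wt (adjusted p = 0.702), -0.03 with hIMP1 Dmut (adjusted p = 0.842) and 0.04 between the constructs (adjusted p = 0.534). The test statistics of the first had the opposite sign to its median, as had its mean (0.0019). No member passed alone, over all genes or adjusted over the list alone. ACTB, the target with which IMP1 was studied as a zipcode-binding protein, had a log2 change of -0.02 ± 0.18 with hIMP1 wt and -0.11 ± 0.18 with hIMP1 Dmut. MYC had changes of -0.01 ± 0.30 and 0.04 ± 0.30, CD44 of -0.10 ± 0.37 and -0.02 ± 0.37, BTRC of -0.02 ± 0.25 and 0.05 ± 0.25, and PPP1R9B, the largest in both, of 0.34 ± 0.24 and 0.47 ± 0.24. The changes of ABCB1 (0.24 and 0.19), MKI67 (-0.26 and -0.33), TCF4 (-0.17 and -0.20), SRF (-0.18 and -0.18), MAPT (-0.14 and -0.24), CTNNB1 (0.10 and 0.06), LIN28B (0.10 and -0.04), SYNCRIP (0.07 and -0.24), FMR1 (0.05 and 0.14), NFKBIA (0.07 and 0.06), PABPC1 (-0.04 and -0.09), E2F1 (-0.04 and -0.17), HMGA2 (0.02 and -0.03) and MITF (-0.01 and 0.26) did not pass the test either. Other probe sets had the opposite sign in at least 1 of these comparisons for BTRC, ABCB1, TCF4, MKI67, SYNCRIP, MITF, MAPT, CTNNB1, FMR1 and E2F1. Among the members that had no kept probe set with a single symbol, and were not tested, were IGF2, H19, MAPK4, GLI1, LIN28A, COL1A2 and PTGS2. The list of proteins of IMP1 granules had medians of 0.02 with hIMP1 wt (adjusted p = 0.372), 1e-04 with hIMP1 Dmut (adjusted p = 0.73) and 0.03 between them (adjusted p = 0.16; 0.0275 without hIMP1 Dmut replicate 1), and with hIMP1 Dmut its mean (-0.02) and test had the opposite sign to the median.

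The responses to the 2 constructs were set against each other over all kept probe sets. Pearson's r between the mean log2 changes was 0.52, where 100 simulations of unchanged groups against the same mock arrays gave 0.50 on average (0.48 to 0.52). The covariance was 0.0395, below the range of 0.0582 to 0.0646 in the simulations (0.061 on average, a difference of -0.0215). The same sign was found for 66.3% of probe sets against 66.7%. The simulation draws arrays independently, while arrays of a number deviated together here, so its ranges need not hold for these arrays. When the mock arrays were not shared, by pairing hIMP1 wt of 1 number with hIMP1 Dmut of the other, r was 0.02 and 0.05. Simulations gave -0.02 to 0.03 for both pairings, so the second value, hIMP1 wt 2 with hIMP1 Dmut 1, lay above them. Each of these pairings rests on a single array per group. Outside HSPA6 the highest change was 1.89 with hIMP1 wt and 2.11 with hIMP1 Dmut.

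**Figure D3:**
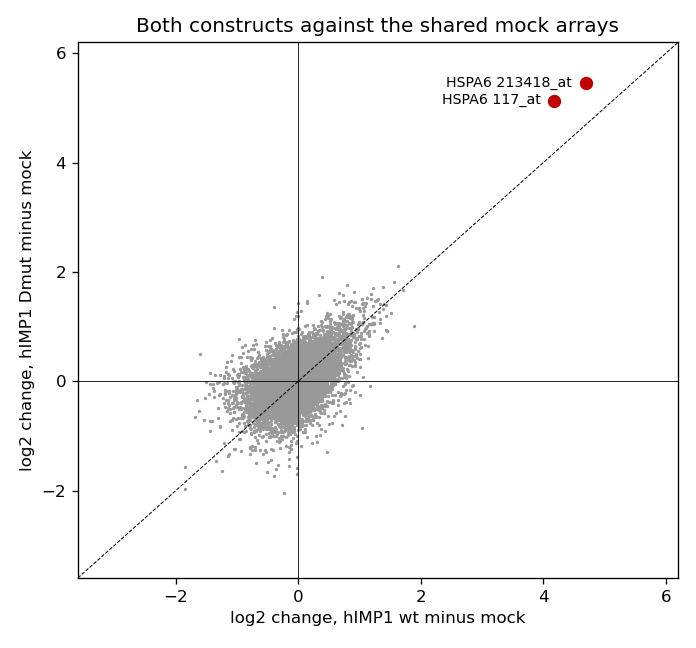
Mean log2 change against the empty vector with hIMP1 wt (x axis) and hIMP1 Dmut (y axis) for 27307 probe sets (grey points), with the 2 probe sets of HSPA6 in red and the line of equal change dashed; no error is drawn. HSPA6 lies at 4.69 and 5.45 (brighter probe set) and at 4.18 and 5.13 (dimmer probe set), apart from the other points. The same mock arrays enter both axes, and r over all points was 0.52. Simulations of unchanged groups gave 0.48 to 0.52, but with arrays drawn independently, so r does not decide whether the responses were shared.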

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

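All tests of explanations in this part were chosen after the results were seen, and some replaced an earlier form whose outcome was already known. In the earlier form, cyclic loess was judged by how much of a list's median it left: -0.0923 of -0.1462 for oxidative phosphorylation, -0.0756 of -0.116 for the proteasome and -0.072 of -0.1035 for the cell cycle, which argued against scaling for all 3 lists. The unfolded protein response was judged for both constructs together by its lowest median within the arrays of a number, -0.0444, which left a difference between numbered sets as an explanation for both. The medians within the arrays of each number were at first also read as a test of hIMP1 Dmut replicate 2 standing apart, and are given here as values only. The later form uses the adjusted p of the list test and each construct apart. In that form a call lost under cyclic loess (proteasome) or with an array left out (unfolded protein response with hIMP1 Dmut) was at first read as pointing to scaling or to a single array. Both are now read as open, because the medians stayed at -0.0756 of -0.116 and at 0.0673 of 0.0978. Calls kept under other scalings (oxidative phosphorylation, the cell cycle, and the unfolded protein response with hIMP1 Dmut) were at first read as arguing against scaling as the whole cause. They are now read as open too, because their p depends on the preset correlation. The readings for these lists and for the unfolded protein response with hIMP1 wt therefore depend on which form is used.

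Between the constructs 7 gene lists were called in the direct test with the preset correlation, and none with an estimated correlation (adjusted p = 0.697 for each). The median differences of hIMP1 wt minus hIMP1 Dmut were 0.0993 for oxidative phosphorylation (adjusted p = 1.55e-05), 0.1389 for the proteasome (2.21e-05), 0.0975 for the cell cycle (6.27e-04), 0.0703 for the secretory pathway (0.0274), -0.1424 for immediate early genes (0.00689), -0.2257 for replication-dependent histones (0.0491) and -0.0768 for KRAB zinc finger genes (0.0498). They are given here because that test is of the difference between the constructs itself, and the calls hold only with the preset correlation. Losing them with an estimated correlation does not by itself show that correlation made them, since that form also uses only 3 residual degrees of freedom. The estimates were above the preset of 0.01 for all 7 lists. In the order above they were 0.51, 0.41, 0.20, 0.13, 0.14, 0.75 and 0.11. Correlation within the lists therefore stays a possible reason for the loss, and the 2 were not tested apart. All 7 calls were lost without hIMP1 wt replicate 2, and those of oxidative phosphorylation, the cell cycle, the secretory pathway, histones and KRAB zinc finger genes also under quantile and cyclic loess scaling. The proteasome call was kept under the 3 other scalings, with a median as low as 0.0704 and an adjusted p of up to 0.0432. The lowest medians there were 0.0311 for oxidative phosphorylation, 0.0524 for the cell cycle and 0.0265 for the secretory pathway. For histones the median stayed between -0.1885 and -0.1693, so that loss is mostly one of p. Within the arrays numbered 1 the medians of the 4 higher lists were near 0 (-0.0232, -0.0018, 0 and -0.0404 for oxidative phosphorylation, the proteasome, the cell cycle and the secretory pathway).

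The lower level of oxidative phosphorylation, proteasome and cell cycle genes with hIMP1 Dmut than with the empty vector was called with the preset correlation, and each call was lost with an estimated one (adjusted p = 0.882 for each). Whether 1 array, hIMP1 Dmut replicate 2, stands apart from its numbered set stays open, since the medians within the arrays numbered 1 (-0.0466, 0.0081 and -0.0714, against -0.26, -0.26 and -0.14 within those numbered 2) are the values that raised the question and do not test it. Without that array the oxidative phosphorylation call (median -0.16, adjusted p = 3.64e-04) and the cell cycle call (-0.16, 0.00336) were kept and the proteasome call was lost (-0.06, 0.751), and without mock replicate 2 all 3 were lost (adjusted p = 0.805, 0.502 and 0.569), but leaving out an array also makes the numbered sets unequal. Under cyclic loess all 3 medians shrank by similar shares. With the preset correlation the camera calls of oxidative phosphorylation (adjusted p = 0.00497) and the cell cycle (0.0396) were kept, while the proteasome call ended (0.101). The lists differ only in which p passed the threshold. These p-values rest on the preset of 0.01, where the estimates were 0.51, 0.20 and 0.41 in that order, so they do not decide on intensity-dependent scaling. Cyclic loess left medians of -0.0923, -0.072 and -0.0756, and a part played by scaling stays open for all 3. An effect of the construct stays open and was not tested apart from the arrays.

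HSPA6 was higher with both constructs. Scaling between arrays is argued against by its lowest log2 change under 3 other scalings, 4.70, far above 1 against an SE of 0.44. A single deviating array is argued against by its lowest change with each array left out in turn, 3.87. That SE is from all 6 arrays and does not apply to the fits with an array left out. A response to hIMP1 wt alone is argued against by the change with hIMP1 Dmut itself, 5.45. The difference between the constructs, -0.76, whose 95% interval ends at 0.22, comes from the same values and is no separate test. As a hypothesis, the change may be a response to protein made from either construct. The series holds no construct of an unrelated protein, so it cannot be set apart from other differences between these plasmids and the empty vector, and a contribution of HSPA7 also stays open.

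The unfolded protein response list was higher with both constructs with the preset correlation, and both calls were lost with an estimated one (adjusted p = 0.545 for hIMP1 wt and 0.882 for hIMP1 Dmut). By fry, the unadjusted p was 0.0805 for hIMP1 wt and 0.157 for hIMP1 Dmut. For hIMP1 wt, scaling is argued against by a median of at least 0.1981 under 3 other scalings, against 0.204 as deposited. The adjusted p there was at most 4.04e-08 (camera, preset correlation). The call was kept with each array left out in turn, with a median of at least 0.14 against 0.20. That leaves the replicate numbers unequal between the groups, and the median was 0.34 within the arrays numbered 1 and 0.08 within those numbered 2. Whether a single array made much of the shift therefore stays open. For hIMP1 Dmut the 3 other scalings left a median of at least 0.07 against 0.10 (camera, preset correlation, adjusted p of at most 0.00177). That p depends on the preset, so a part played by scaling stays open. A single array stays open for this construct as well. The call ended without mock replicate 1 (adjusted p = 0.331) or hIMP1 Dmut replicate 1 (0.389), but the median was still 0.085 and 0.0673 against 0.0978, so the rise in p does not point to either array, and leaving out an array also leaves the replicate numbers unequal between the groups.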

How the results depend on the processing

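Cyclic loess scaling, the replicate block together with an estimated correlation, and the lists without HSPA6 or without secretory members were chosen after seeing the data. Of 3992 values for 239 named gene results, 3984 kept their side of the threshold and 8 lost the call, all for HSPA6. The 34 values of HSPA6 kept their sign, but of the 3958 values for the 237 results not called, 120 turned sign, in 70 results. Of 1566 values for 75 list results, 1420 kept their side and, where called in either setting, their direction, 86 lost the call, 41 gained it and 19 changed direction with a call in either setting. Of the 1188 values for the 57 list results not called, 118 turned the sign of the median, in 49 results. Of 133 values for counts and agreement, 96 stayed within the limits set. The causes were not tested. A low signal over background limits HSPA6 on the mock arrays. No scaling moved the median of all genes by more than 0.0434. The robust prior was not applied to list tests, and the 4-array fits give no agreement between responses.

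With hIMP1 wt against the empty vector, 2 probe sets were called. The count was 1 with an offset at the 10th percentile, 1 above the 75th percentile of signal, 0 with only the 4 arrays, 0 without an intensity trend, and 28 at 2-fold with an unadjusted p under 0.01. With hIMP1 Dmut, 2 became 1 above the 75th percentile, 0 without a trend and 42 at 2-fold with an unadjusted p. Between the constructs, 0 became 30 by that rule. Leaving out each array in turn gave 0 to 3, 0 to 2 and 0 to 0 probe sets. An array left alone in its group was assumed to vary like the others.

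With an estimated correlation 0, 0 and 0 lists were called, where the preset gave 3, 8 and 7, and 0, 0 and 0 with the replicate block added. Between the constructs, 7 lists became 2 under quantile scaling, 3 under cyclic loess, 4 without a filter and 4 without a trend. Leaving out each array in turn gave 3 to 11, 4 to 10 and 0 to 11 lists. Agreement between the responses was 0.52, 0.542 above the 75th percentile, and 0.264 to 0.766 with each array left out.

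The median of ribosomal protein genes with hIMP1 Dmut was -5e-04 under quantile scaling, with the test reversed, and 0.0194 under cyclic loess, where it was -0.0643 between the constructs. With each array left out it ranged from -0.2517 to 0.1002 for hIMP1 Dmut and from -0.2364 to 0.1241 for hIMP1 wt. With hIMP1 wt, the ranges were -0.1733 to 0.1274 for oxidative phosphorylation and -0.1545 to 0.1116 for the cell cycle. With hIMP1 Dmut, they were -0.115 to 0.2754 for heat shock, -0.3958 to 0.6042 for histones, -0.1469 to 0.2414 for adhesion and matrix, and -0.2267 to 0.1176 for glycolysis. Between the constructs, they were -0.0559 to 0.2807 for oxidative phosphorylation, -0.0111 to 0.2414 for the cell cycle, -0.6526 to 0.1807 for histones, 0.0069 to 0.1223 for the secretory list (test reversed without hIMP1 Dmut replicate 2), -0.2197 to 0.1437 for heat shock, and -0.2449 to 0.155 for adhesion and matrix. Leaving out an array makes the numbered sets unequal between groups, so these medians also hold the difference between the sets.

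Arrays of the same replicate number deviated together, a difference that the main fit leaves in its residual spread. The labels do not say whether the numbers mark paired samples, and 2 numbers are too few to show it. Deviations from group means correlated at 0.464 (mock and hIMP1 wt), 0.20 (mock and hIMP1 Dmut) and 0.217 (hIMP1 wt and hIMP1 Dmut), and 6 of 6 arrays correlated best with an array of their own number. With the replicate number as a block, the counts were 2, 2 and 0 probe sets (705, 1134 and 870 with an unadjusted p under 0.05, against 281, 387 and 337 without it) and 3, 8 and 10 lists. The 3 lists gained between the constructs were p53 targets (adjusted p = 0.0455), the actin cytoskeleton (0.0455) and cholesterol synthesis (0.0336). With the block and an estimated correlation these calls were lost, as were all others. The block fit has 2 residual degrees of freedom.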

Other observations

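No explanation was tested in this part. The list calls given here were made with the preset correlation. On all 6 arrays no list was called with an estimated correlation, which for ribosomal protein genes was 0.81.

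Several gene groups showed no call in any of the 3 comparisons at the settings used, though some were called under an alternative. With the replicate number as a block, camera called p53 targets, the actin cytoskeleton and cholesterol synthesis between the constructs (adjusted p = 0.0455, 0.0455 and 0.0336). With the block and an estimated correlation no list was called. Of the 57 list results without a call, 46 turned the sign of their median and 24 were called in at least 1 of the fits that left out an array, so many of these medians depend on single arrays. Between the constructs, p53 targets, cholesterol synthesis and the actin cytoskeleton lay near the threshold: p53 targets passed among probe sets above the 75th percentile (adjusted p = 0.028), and without hIMP1 wt replicate 1 cholesterol synthesis and the actin list passed (0.0156 for each), as did glycolysis (0.00381). Against the empty vector, the cholesterol, actin and glycolysis lists passed with hIMP1 wt without hIMP1 wt replicate 1 (adjusted p = 0.0226, 0.0147 and 0.00173), and the cholesterol and glycolysis lists without mock replicate 2 (0.00632 and 2.29e-05). With hIMP1 Dmut, glycolysis passed downwards without mock replicate 1 (adjusted p = 0.00321) and upwards without mock replicate 2 (0.0103). The adhesion and matrix list passed upwards with hIMP1 wt without mock replicate 2 (median 0.16, adjusted p = 0.0483). With hIMP1 Dmut it passed upwards without hIMP1 Dmut replicate 1 (0.24, adjusted p = 0.00462) or mock replicate 2 (0.13, adjusted p = 0.016) and downwards without hIMP1 Dmut replicate 2 (-0.15, adjusted p = 0.0449). Between the constructs it passed downwards without hIMP1 Dmut replicate 1 (-0.24, adjusted p = 0.011) and upwards without hIMP1 Dmut replicate 2 (0.15, adjusted p = 0.017). The list of p53 targets had medians of -0.05 with hIMP1 wt (adjusted p = 0.338) and 0.04 with hIMP1 Dmut (adjusted p = 0.648), and 20 of 24 genes were lower with hIMP1 wt than with hIMP1 Dmut (median -0.13, adjusted p = 0.0734), by -0.11 within the arrays numbered 1 and -0.12 within those numbered 2. Of 21 genes of cholesterol synthesis 18 were higher with hIMP1 wt than with hIMP1 Dmut (median 0.07, adjusted p = 0.0734), and their medians against the empty vector were 0.09 (adjusted p = 0.338) and -0.02 (adjusted p = 0.648). Genes of the actin cytoskeleton had medians of 0.01 (adjusted p = 0.324), -0.01 (adjusted p = 0.73) and, between the constructs, 0.07 (adjusted p = 0.0683). Interferon-stimulated genes had medians of -0.02 (adjusted p = 0.956) with hIMP1 wt and -0.06 (adjusted p = 0.476) with hIMP1 Dmut, and 0.07 between them (adjusted p = 0.306). Glycolysis genes had medians of 0.02 (adjusted p = 0.338), -0.05 (adjusted p = 0.73) and 0.05 (adjusted p = 0.106), cell adhesion and matrix genes -0.03 (adjusted p = 0.843), 0.02 (adjusted p = 0.572) and -0.06 (adjusted p = 0.697), and ubiquitin conjugation genes 0.0045 (adjusted p = 0.567), 0.03 (adjusted p = 0.331) and -0.02 (adjusted p = 0.678), in the same order.

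Lists called in some comparisons had these medians in the others. With hIMP1 wt against the empty vector, ribosomal protein genes had a median of -0.07 (adjusted p = 0.122), oxidative phosphorylation -0.03 (0.843), proteasome 0.03 (0.381), cell cycle -0.0023 (0.956), histones -0.12 (0.338), KRAB zinc fingers -0.01 (0.826), immediate early genes 0.05 (0.381) and Golgi 0.05 (0.163). All of these except Golgi were called with hIMP1 wt in at least 1 fit that left out an array. Without mock replicate 1, ribosomal protein genes had a median of -0.24 (adjusted p = 1.32e-10), oxidative phosphorylation -0.15 (6.45e-04) and immediate early genes 0.28 (0.0108), and histones stood at 0.41 without a call (0.0794). Without mock replicate 2, ribosomal protein genes had 0.12 (adjusted p = 2.11e-04), oxidative phosphorylation 0.10 (0.0016), proteasome 0.10 (0.036), histones -0.55 (4.27e-06) and KRAB zinc fingers -0.13 (0.024). Without hIMP1 wt replicate 1, oxidative phosphorylation had 0.13 (adjusted p = 2.83e-05), proteasome 0.10 (0.0118), the cell cycle 0.11 (0.00424) and histones -0.57 (2.83e-05). Without hIMP1 wt replicate 2, ribosomal protein genes had -0.19 (adjusted p = 1.06e-05), oxidative phosphorylation -0.17 (4.27e-06), the cell cycle -0.15 (0.00683) and immediate early genes 0.26 (0.0187). Ribosomal protein genes were also called among probe sets above the 75th percentile (-0.08, adjusted p = 0.00572) and under cyclic loess (-0.06, adjusted p = 0.00261). With hIMP1 Dmut, the secretory list had a median of 0.01 (adjusted p = 0.572), histones 0.17 (0.572) and KRAB zinc fingers 0.07 (0.192). The secretory list was called without hIMP1 Dmut replicate 2 (0.10, adjusted p = 0.00336). Histones were called upwards without mock replicate 1 (0.60, adjusted p = 0.00123) or hIMP1 Dmut replicate 2 (0.34, adjusted p = 0.0148) and downwards without mock replicate 2 (-0.40, adjusted p = 0.0105). KRAB zinc fingers were called without mock replicate 1 (0.14, adjusted p = 0.00321) or hIMP1 Dmut replicate 2 (0.13, adjusted p = 0.0449) and among probe sets above the 75th percentile (0.12, adjusted p = 0.00173). Between the constructs, the medians were 0.02 for ribosomal protein genes (adjusted p = 0.345) and -0.01 for Golgi (0.534), and the ribosomal list was called upwards without hIMP1 wt replicate 1 (0.15, adjusted p = 6.46e-04) and downwards under cyclic loess (-0.06, adjusted p = 1.45e-04).

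Markers of other cell types and of kidney epithelium showed no call either. Kidney epithelial markers had medians of 0.07 (adjusted p = 0.631), 0.10 (0.572) and 0.02 (0.899) for hIMP1 wt, hIMP1 Dmut and the difference between them. Neuronal and chromaffin markers had -0.06 (adjusted p = 0.381), -0.14 (0.192) and 0.02 (0.697), fibroblast markers -0.01 (0.956), 0.01 (0.73) and -0.16 (0.697), and snoRNA host genes -0.07 (0.956), -0.04 (0.842) and 0.02 (0.728). The 5 blood cell markers had 0.09 (adjusted p = 0.956), 0.17 (0.424) and -0.20 (0.368). Their median on single arrays ranged from -0.44 on mock replicate 2 to 0.54 on hIMP1 Dmut replicate 2.

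The median and the mean or the test differed in sign for several of these lists. With hIMP1 wt, the test pointed up while the median was negative for interferon-stimulated genes, adhesion and matrix genes and snoRNA host genes, and the mean of the blood cell markers (-0.04) was opposite to their median. With hIMP1 Dmut, the mean of the actin list (4e-04) was opposite to its median. Between the constructs, the means of the heat shock list (-0.02), the kidney epithelial markers (-0.06) and the neuronal and chromaffin markers (-0.02) were opposite to their medians.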
